A study of Mus musculus with 8 samples.

How the data were processed

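RNA from the back-skin epidermis of mice at postnatal day 5 was sequenced in 8 libraries, 4 from control and 4 from experimental animals, per the labels. Per the labels' protocols, RNA was purified on RNeasy columns and libraries were made with the NEBNext Ultra kit. The submitters' processing notes name STAR, SAMtools 1.9, Salmon 0.14.0 and DESeq, and the builds GRCm38 and mm10, without saying which tool made which table. The authors named DESeq2 as their tool for expression and MAJIQ for splicing.

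The expression table as deposited by the authors holds log2 values of TPM per gene, without batch correction per its name. Its scale was tested against the mean normalized counts in the authors' deposited table. The count per kilobase divided by 2 to the power of the listed value was flat over the range, 1.02 to 1.04 times that of the highest bin over 400 genes. Subtracting 1 from that power raised the ratio to 1.78 in the lowest bin. The values were therefore read as log2 TPM with entries at or under 1 TPM listed at 0. A 0 thus means 1 TPM or less and not absence. Converted values summed to between 83.2% and 86.0% of the full TPM total per library. Of 21690 gene identifiers, 21662 matched a symbol in the reference names. Of all entries 49.6% were 0, and 9484 genes were at 0 in every library. TPM carries no depth, so sequencing depth was unknown, and no counting interval could be given.

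The authors' deposited differential expression table gives a mean normalized count signal over samples, a log2 fold change with its standard error, a Wald score, and p-values with adjusted p-values, per the file headers. Its rows are genes with adjusted p under 0.05 and a fold change below 0; whether other genes were filtered out is not given in the sources used here. The authors' deposited MAJIQ table gives for each junction or intron a PSI fraction per group, the expected difference (experimental minus control), and the posterior probability score that the absolute difference is at least 0.15, per the file headers. MAJIQ combined the libraries of a group, so no library's own PSI was used here. Of 1203 junction entries 100 had no value; repeated entries of a junction were counted once. Junction coordinates are those of the authors' table. Of 444 distinct spliced junctions not marked as absent from the annotation, 99.6% had both ends at exon boundaries of GENCODE M21 (GRCm38). Exons were taken as the bases between the 2 inclusion junctions of a cassette or mutually exclusive event and looked up in that annotation.

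Columns of the expression table carry a group and a number that no label explains, but no replicate number that matches the labels. Libraries were therefore assigned to groups, and the numbers 1 to 4 within a group are names in the order of the table. Libraries were not paired.

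TPM values were set to at least 1 and transformed as log2(TPM + 1), and genes with mean TPM of at least 1 were tested (10682). The design assumed values of log2(TPM + 1), and the values were turned back to TPM first. A fold change on this scale understates the change of low genes. limma 3.58.1 in R 4.3.3 was fitted with group as the only term (eBayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Of 29 gene lists fixed before the data were examined, 23 with at least 4 tested members entered limma's camera test with a preset correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run beside it. Single values were compared by exact permutation and gene sets by Fisher's exact test (scipy 1.17.1, pandas 2.3.3, numpy 2.4.6, Python 3.11.15); figures used matplotlib 3.10.9. On simulated data with the real means and spreads, limma recovered 46% of genes changed by 1 on the log2 scale and 90% of those changed by 2, over 10638 genes, and 8.72% of the calls were false. The changed genes were drawn only from genes well above the floor, and noise was independent between genes. These rates may therefore be too favourable for low genes and for genes that vary together.

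Genes were named by a rule fixed before the data were examined: Esrp1 and Esrp2; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 5 TPM; up to 4 passing members of each list, or the 2 of lowest p as values; the 12 genes with the largest change of PSI; and every literature target in the MAJIQ table. Genes with no name beyond an identifier or clone number were passed over. Means are given with SD over libraries, and values per library where any entry of the group was at the floor.

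Alternatives fixed in advance were other pseudocounts (0.1 and 0.5 TPM), no filter or a mean of at least 5 TPM, quantile normalization, median centring, no variance trend, library weights, leaving out each library, other thresholds and other backgrounds. Library weights used limma's gene-by-gene method, since the default did not converge. Alternatives chosen after seeing the data were genes above the floor in every library, a residual principal component or sex as a covariate, and leaving out pairs of libraries. The fit with replicate number as a block was not run.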

Results

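Epidermis from the back skin of mice at postnatal day 5 was profiled by RNA sequencing to ask how the epidermal transcriptome depends on ESRP1 and ESRP2, a pair of epithelial RNA-binding proteins that regulate splicing. The 8 libraries fell into 4 control and 4 experimental libraries, which the labels call biological replicates. Per the labels, controls carried floxed Esrp1 alleles and null Esrp2 alleles, without Cre. Experimental animals carried the same alleles with a doxycycline-driven Cre under a keratin 5 transactivator. The mothers of both groups received doxycycline chow from embryonic day 17. By genotype both groups lacked Esrp2, so the comparison was of the added deletion in Esrp1, together with any effect of the transgenes. Expression was given as TPM, a length-normalized share of transcripts, for 21690 genes, with values at or under 1 TPM listed at 0. Between 10523 and 11640 genes per control library and between 10401 and 11077 per experimental library lay above 1 TPM. TPM keeps no sequencing depth, so the depth of each library was unknown. The 10 most abundant genes took 18.2% ± 0.37 of the TPM in control libraries and 23.6% ± 1.07 in experimental ones (SD, n = 4 each). Mitochondrially encoded genes took 18.2% and 17.5% in experimental libraries 2 and 4, against 10.6% to 12.6% in the other 6 libraries.

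Esrp1 transcript was lower in every experimental library than in any control. The gene (ENSMUSG00000040728.15; chromosome 4, 11331933 to 11386783, minus strand, GRCm38) stood at 135, 131, 133 and 162 TPM in the control libraries and at 65.0, 49.8, 75.6 and 66.5 TPM in the experimental ones. The group means were 140.3 ± 14.6 and 64.2 ± 10.7 TPM (SD, n = 4 each), a 2.18-fold lower level. The log2 change was -1.13 (SE 0.17, limma adjusted p = 0.0112), and an exact permutation test, two-sided, gave p = 0.0286, the smallest that 4 against 4 libraries allow. The deposited MAJIQ comparison placed the loss within the gene. The junction from exon 6 to exon 7 fell from a PSI (the share of reads at a splice site that use the junction) of 0.842 to 0.072, and that from exon 9 to exon 10 from 0.953 to 0.147. A junction absent from the annotation, from 11361255 to 11366908, joined exon 6 to exon 10 with a PSI of 0.001 in controls and 0.828 in experimental epidermis. It left out exons 7, 8 and 9, together 287 bases, which is no multiple of 3. Esrp2 read 3.07, 0, 2.14 and 3.31 TPM in control libraries and 4.98, 3.25, 5.28 and 4.22 TPM in experimental ones, and this difference did not pass the test (limma adjusted p = 0.176). Whether these Esrp2 reads lie in the deleted part of the gene was not tested.

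**Figure D1:**
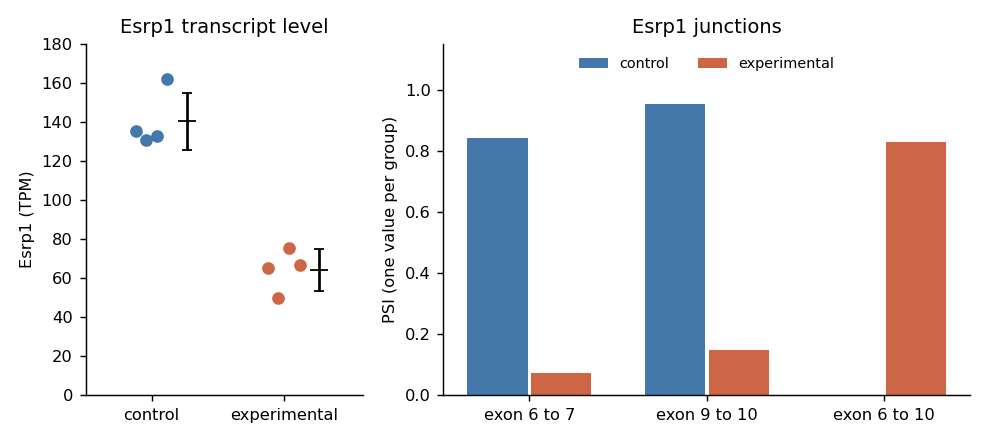
Left: Esrp1 level in TPM in each library (points) with the group mean and SD (n = 4 each). Right: PSI of 3 Esrp1 junctions, 1 value per group from the authors' MAJIQ table; the junction from exon 6 to exon 10 stood at 0.001 in controls and 0.828 in experimental epidermis.

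The largest rises in experimental epidermis included Sprr2d, Sprr1b, Krt6b and Defb14, and the largest falls included Calhm4, Krt15 and Sccpdh. Of 10682 genes tested, 263 passed the threshold of adjusted p under 0.05 in limma, 98 higher and 165 lower. The median gene changed by -0.18 on the log2 scale. Centring each library on its median added 0.21 to every log2 change, which moved the median gene to 0.03, and gave 283 higher and 102 lower genes among 385, and quantile normalization gave 269 higher and 117 lower among 386. The split between rises and falls therefore depended on the scaling. Groups did not overlap for 12.6% of genes, against 2.86% by chance.

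The largest rise was that of Sprr2d (ENSMUSG00000042212.3; chromosome 3, 92339140 to 92340873), which encodes a small proline-rich component of the cornified envelope. It went from 5.11 ± 1.91 to 288 ± 13.8 TPM (SD, n = 4 each), a log2 change of 5.63 (SE 0.24, limma adjusted p = 3.37e-06). Its relatives Sprr1b and Sprr2h rose from 26.2 ± 8.77 to 271 ± 116 TPM and from 50.6 ± 16.1 to 370.4 ± 31.6 TPM. Sprr2e was listed at 0 in all 4 controls and averaged 13.6 ± 1.76 TPM in experimental libraries, at least 13.6-fold higher against the floor of 1 TPM per library. Lce3e, a late cornified envelope gene, rose 7.62-fold to 27.8 ± 2.14 TPM, and Rptn, which encodes the envelope protein repetin, rose 8.47-fold to 107 ± 30.8 TPM. Defb14, an antimicrobial beta-defensin, rose 5.74-fold to 348 ± 66.8 TPM. Krt6b, a keratin of wounded and hyperproliferative epidermis, stood at 7.27, 4.04, 1.54 and 0 TPM in controls and 51.9 ± 27.6 TPM in experimental libraries. The other large rises were Spink7 and Spink12, which encode Kazal-type protease inhibitors (24.2-fold and 9.62-fold), Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis (12.3-fold), and Krt12, best known as the corneal keratin (11.5-fold). Krt12 reached 63.9 to 75.5 TPM in 3 experimental libraries and 10.3 TPM in experimental library 4. All 12 kept adjusted p under 0.05 with centred and quantile-normalized values, and 10 to 12 did when 1 library was left out. Krt12 did not pass without the filter on low values, and without experimental libraries 2 and 4 Krt6b, Sprr1b, Krt12, Lce3e and Defb14 did not. Sprr2 and Lce genes form families of similar copies, so how reads were divided among members is uncertain.

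**Figure D2:**
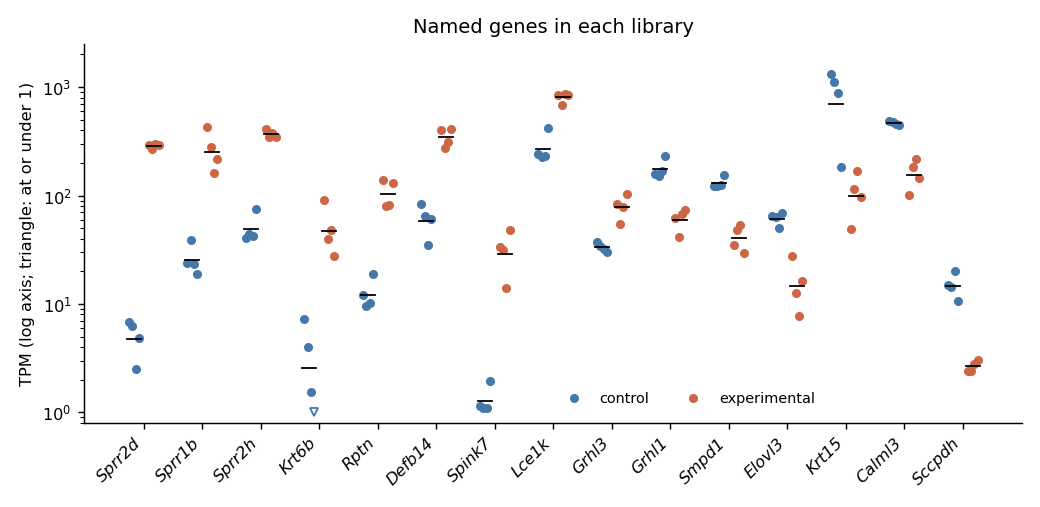
TPM of 15 named genes in each library on a log axis, control in blue and experimental in orange, with the mean of the log values as a bar (n = 4 each); an open triangle marks a value at or under 1 TPM. Sprr2d stood at 268 to 297 TPM in the experimental libraries, and Grhl1 and Grhl3 moved in opposite directions.

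The list of stress keratins and alarm genes, fixed before the data were examined, rose as a group. Of its 33 tested members 15 rose and none fell (20 rises adjusted over the list alone), with a median log2 change of 1.01. Log2 changes were above 0 for 24 of the 33 and below 0 for 9. The expression data held 48 members, and the rest were under the filter. In limma's camera test with the preset correlation the list stood above other genes (adjusted p = 5.75e-35 over 23 lists), and this call held with an estimated correlation (adjusted p = 0.0056). With estimated correlation and centred values it did not pass (adjusted p = 0.0944). The list's mean log2 level was 4.65 to 5.13 in controls and 6.11 to 6.42 in experimental libraries (exact permutation test, p = 0.0286, adjusted p = 0.257 over 27 lists). Among its members were Sprr2d, Sprr2h, Sprr2e and Lce3f, the last at 1.31 ± 0.22 and 8.17 ± 1.18 TPM (SD, n = 4 each).

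The cornified envelope list, whose proteins form the outer shell of dead surface keratinocytes, held 3 rises and no falls among 32 tested genes (11 rises adjusted over the list alone). Besides Rptn these were Lce1k, which rose 2.89-fold to 810.0 ± 87.5 TPM, and Lce1j, from 229 ± 48.3 to 488 ± 114 TPM (SD, n = 4 each). The list held 4 rises with centring and 8 with quantile normalization. It held 18 without control libraries 3 and 4 and 2 without control libraries 1 and 2. Its camera call (adjusted p = 5.46e-16) was lost with an estimated correlation (adjusted p = 0.388). Control library 4 lay above the other controls on this list, at a mean log2 level of 10.1 against 9.42 to 9.47, and within the range of the experimental libraries, 9.92 to 10.3 (exact permutation test, p = 0.0857, adjusted p = 0.331 over 27 lists). Suprabasal keratinocyte genes moved both ways. Serpinb2, a serine protease inhibitor, rose 2.04-fold to 155 ± 31.9 TPM, and Calml3, a calmodulin-like epithelial protein, fell 2.87-fold to 163 ± 50.6 TPM, while 10 of 12 members did not pass. The camera call of that list (adjusted p = 0.00202) was lost with an estimated correlation (adjusted p = 0.388).

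Genes of epidermal lipid synthesis moved both ways. Of 31 tested barrier lipid enzymes 1 rose and 2 fell (6 and 5 adjusted over the list alone). With centring 3 rose and 2 fell, and with quantile normalization 4 rose and 2 fell. Elovl1, an elongase of very long fatty acids, rose 1.85-fold to 1227 ± 157 TPM. Elovl3, the elongase of hair follicle and sebaceous gland, fell 3.83-fold to 16.2 ± 8.45 TPM, and Smpd1, acid sphingomyelinase, fell 3.17-fold to 41.6 ± 11.3 TPM (SD, n = 4 each). The list's median log2 change was 0.13 and its mean was -0.06, and its upward camera call (adjusted p = 0.00174) was lost with an estimated correlation (adjusted p = 0.478). In sterol biosynthesis 1 of 24 tested genes rose, Stard4, a sterol transport protein, from 26.0 ± 5.58 to 47.4 ± 6.63 TPM; centring raised the number to 10. The camera call for higher sterol genes (adjusted p = 2.47e-07) did not hold with an estimated correlation (adjusted p = 0.478).

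Among the falls, Krt15, a keratin of basal and follicle stem cells, went from 877 ± 497 to 108 ± 49.9 TPM (SD, n = 4 each; log2 change -2.82, SE 0.59, limma adjusted p = 0.0361). It read 1323, 1124, 876 and 184 TPM in the control libraries. Sccpdh, a putative saccharopine dehydrogenase, fell 5.64-fold to 2.67 ± 0.30 TPM (log2 change -2.10, SE 0.20, limma adjusted p = 0.000734). Pnpla5, a patatin-like lipase, fell 5.99-fold, Aadacl4, related to arylacetamide deacetylase, 5.17-fold, Ces4a, a carboxylesterase, 4.44-fold, and Pla2g3, a secreted phospholipase, 3.88-fold. Hsd3b6, a steroid dehydrogenase, stood at 33.6, 28.4, 5.57 and 5.38 TPM in controls and 2.10, 2.44, 0 and 1.38 TPM in experimental libraries. Calhm4 fell 7.86-fold, the glutamine transporter gene Slc38a3 6.12-fold, Pxylp1 5.33-fold and the insulin-like growth factor binding protein gene Igfbp3 4.87-fold. Calhm4 read 27.0, 47.3, 81.2 and 150.8 TPM in the control libraries and 21.2, 2.88, 6.49 and 8.33 TPM in the experimental ones. Slc38a3 read 9.97, 14.1, 33.2 and 52.3 TPM in controls and 6.03, 2.03, 3.69 and 6.16 TPM in experimental libraries. After centring, 8 of these 12 largest falls still passed, and Calhm4, Krt15, Hsd3b6 and Slc38a3 did not; without the filter on low values Pnpla5 and Igfbp3 were lost as well. Leaving out 1 library kept 4 to 12 of them, and leaving out experimental libraries 2 and 4 kept 0.

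Hair follicle and hair shaft genes were lower by a median log2 change of -1.73, with all 35 tested members below 0, but none passed over all genes (18 falls adjusted over the list alone). Hoxc13, a regulator of hair keratin genes, read 30.8 ± 17.1 and 8.45 ± 4.61 TPM (limma adjusted p = 0.0584), and Msx2 42.6 ± 18.8 and 15.4 ± 6.94 TPM (limma adjusted p = 0.0636). The camera call of the list (adjusted p = 3.1e-09) was lost with an estimated correlation (adjusted p = 0.478) and without control libraries 3 and 4 (adjusted p = 0.659), which had the highest hair levels, 8.70 and 8.99 on the mean log2 scale against 6.97 and 7.83 in control libraries 1 and 2. The experimental libraries lay between 4.95 and 7.41. Without control libraries 1 and 2 the downward call held at the preset correlation (camera adjusted p = 1.42e-16). In that fit 12 hair genes fell, against 2 without control libraries 3 and 4. In the sebaceous gland list 1 of 10 members fell, Elovl3 (4 adjusted over the list alone), with all 10 members below 0 and a median log2 change of -1.10. Its camera call (adjusted p = 0.000474) was lost with an estimated correlation (adjusted p = 0.478) and without control libraries 1 and 2 (adjusted p = 0.0518), which had the highest sebaceous levels. Without control libraries 3 and 4 the call held at the preset correlation (camera adjusted p = 7.83e-05). In that fit 8 sebaceous genes fell, against 1 without control libraries 1 and 2. Of 13 basal keratinocyte genes Krt15 alone fell, and of 28 cell cycle genes none passed. These lists differed widely among controls: basal genes had mean log2 levels of 6.21, 5.92, 5.13 and 3.63 in control libraries 1 to 4, and cell cycle genes 4.19, 3.59, 2.20 and 1.49. The levels of both lists fell in the order of the numbers in the control column names, which no label explains. No label gives litter, batch or dissection, so what separates these controls is unknown, and control means and SDs span this range. Control library 4 was the only control with a Y-linked gene above the floor, but both lists already fell from control library 1 to 3. Without control libraries 3 and 4, 10 basal and 26 cell cycle genes fell (camera at the preset correlation, adjusted p = 7.83e-05 and 2.61e-11). Without control libraries 1 and 2 the cell cycle list stood above other genes (camera at the preset correlation, adjusted p = 9.16e-09), with no basal gene past the threshold. These calls were not repeated with an estimated correlation. Over all libraries that estimate was 0.922 for basal and 0.923 for cell cycle genes, far above the preset value. The camera p-values of these fits may therefore be far too small. Rrm1 and Bub1b, the cell cycle genes of lowest p, did not pass: Rrm1 read 9.46 ± 7.06 and 4.62 ± 0.39 TPM in control and experimental libraries (SD, n = 4 each), and Bub1b 8.02, 4.94, 1.53 and 0 TPM in controls and 1.73 ± 0.28 TPM in experimental libraries. Without control libraries 3 and 4 the number of genes past the threshold was 2595, and without control libraries 1 and 2 it was 544.

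**Figure D3:**
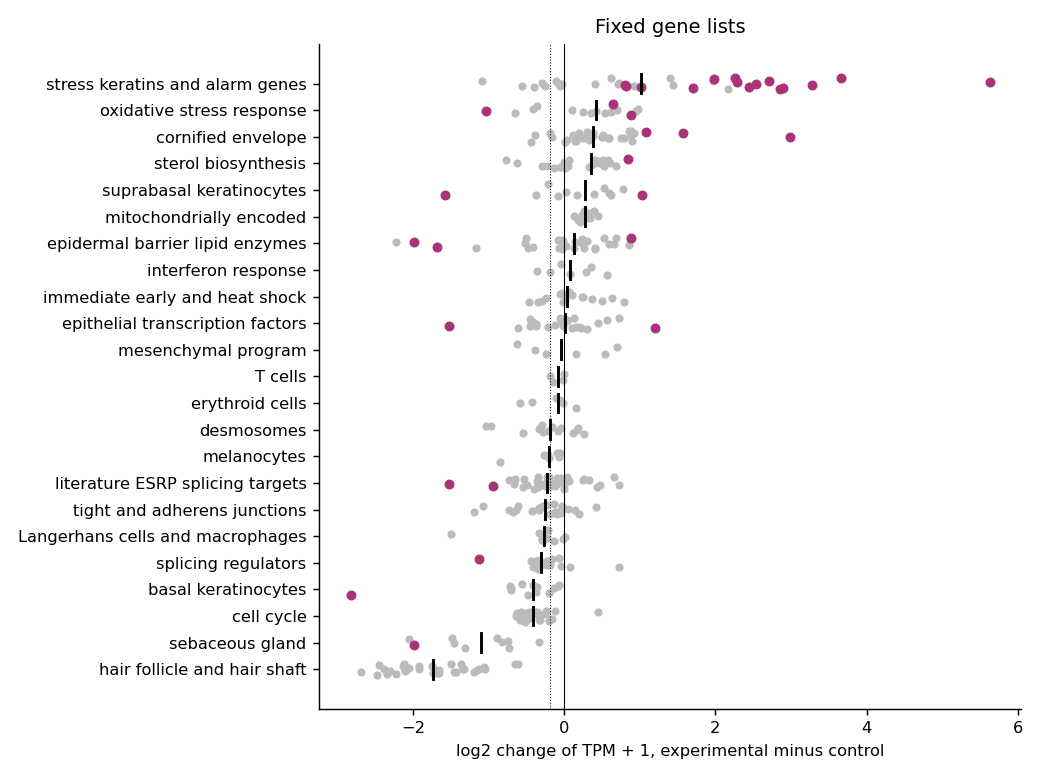
Log2 change of TPM + 1, experimental minus control, of each tested member of the fixed gene lists; purple points passed limma at adjusted p under 0.05, black bars are list medians, and the dotted line is the median of all tested genes, -0.18. The alarm gene list has a median of 1.01 and the hair list one of -1.73, with no hair gene past the threshold.

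Grainyhead-like transcription factors, which govern epithelial barrier genes, moved in opposite directions. Grhl1 (ENSMUSG00000020656.16; chromosome 12, 24572283 to 24617391) fell from 178 ± 36.5 to 61.4 ± 13.8 TPM (log2 change -1.53, SE 0.22, limma adjusted p = 0.0077), and Grhl3 rose from 33.6 ± 3.14 to 79.9 ± 19.8 TPM (log2 change 1.20, SE 0.20, limma adjusted p = 0.0156; SD, n = 4 each). The other 22 tested epithelial transcription factors did not pass. Their list had a median log2 change of 0.01 and a mean of -0.02, and its upward camera call (adjusted p = 0.0373) was lost with an estimated correlation (adjusted p = 0.478). In the oxidative stress list 2 of 15 genes rose and 1 fell. Srxn1, which encodes sulfiredoxin, rose 1.92-fold to 20.5 ± 2.45 TPM. Gsta3, a glutathione transferase gene, was above the floor in all 4 experimental libraries at 2.22 ± 0.27 TPM and in 1 control. Osgin1 fell from 3.09 ± 0.34 TPM to 1 TPM or less, listed at 0, in all 4 experimental libraries. Against that floor it was at least 3.09-fold lower. That list's camera call (adjusted p = 0.000363) was lost with an estimated correlation (adjusted p = 0.388).

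Genes of cell adhesion did not pass. Among 26 tight and adherens junction genes Marveld3 read 5.41 ± 0.19 and 3.09 ± 0.91 TPM and Cldn12 14.7 ± 7.82 and 6.15 ± 1.88 TPM, and among 14 desmosome genes Pkp3 read 206 ± 48.6 and 107 ± 29.9 TPM and Dsc2 12.4 ± 8.04 and 5.22 ± 2.77 TPM, in control and experimental libraries (SD, n = 4 each). Of 6 tested mesenchymal genes none passed; S100a4 read 48.6 ± 24.2 and 72.2 ± 21.6 TPM and Snai2 5.38 ± 3.58 and 2.56 ± 0.19 TPM. None of 7 interferon response genes or 16 immediate early and heat shock genes passed. The camera call of the immediate early list (adjusted p = 0.00927) was lost with an estimated correlation (adjusted p = 0.588). Among 21 splicing regulators Esrp1 alone changed. In the list of literature ESRP splicing targets 2 of 45 genes fell, Grhl1 and Mpzl1, the latter from 11.5 ± 1.00 to 5.61 ± 1.26 TPM.

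No single marker gene of other cell types passed. None of 7 melanocyte, 11 Langerhans cell and macrophage, 4 T cell or 6 erythroid genes passed. Tyr, the melanin synthesis enzyme, read 2.96 ± 1.57 and 2.31 ± 0.78 TPM in control and experimental libraries (SD, n = 4 each), and Ptprc, the pan-leukocyte marker, 3.32, 3.17, 2.30 and 0 TPM in controls and from 0 to 2.56 TPM in experimental libraries. Fibroblast, skeletal muscle and adipocyte markers had 2 members each above the filter and endothelial and mast cell or granulocyte markers had none. Postn, a fibroblast matrix gene, read 65.8 ± 42.0 and 51.7 ± 5.97 TPM, and Fabp4, an adipocyte lipid carrier, 527 ± 445 and 216 ± 97.3 TPM. The mean of the 2 adipocyte genes was lower in every experimental library than in any control, by 0.83 on the log2 scale (exact permutation test, p = 0.0286, adjusted p = 0.257 over 27 lists). All 13 mitochondrially encoded genes had log2 changes above 0 (median 0.28) and none passed. Their camera call (adjusted p = 2.43e-05) was lost with an estimated correlation (adjusted p = 0.478) and without experimental libraries 2 and 4 (adjusted p = 0.771). A Y-linked gene was above the floor in 1 control, library 4, and in 2 experimental libraries, 1 and 3. Ddx3y read 8.86 TPM in that control, 10.1 and 13.2 TPM in those experimental libraries, and was listed at 0 elsewhere. The experimental libraries without it, 2 and 4, were those with more mitochondrial transcripts.

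The authors' deposited differential expression table was set beside these calls. It listed 748 genes, each with a log2 fold change below 0 and the largest adjusted p at 0.0499, so rises could not be compared with it. Of its genes 104 were listed at 0 TPM in every library, and 503 entered the limma fit. All 503 had a log2 change below 0 there, against 74.5% of all tested genes. The table holds genes already selected as lower in the same study, so this shared sign is no independent support. Of the 503, 162 passed the limma threshold, and 162 of the 165 genes called lower by limma were in the table. The exceptions, Abhd8, Acsl5 and Arl4c, are named for that reason and were chosen after their values were seen. Log2 changes correlated across genes with Pearson r = 0.80 and a Spearman coefficient of 0.85, although genes are not independent replicates. In the authors' deposited table Esrp1 had a log2 fold change of -0.98 (adjusted p = 0.000681), Grhl1 one of -1.41 (adjusted p = 5.37e-05) and Krt15 one of -2.73 (adjusted p = 5.6e-06). The authors' deposited table also called lower genes that did not pass limma here, among them Hoxc13 (adjusted p = 0.0138), Msx2 (adjusted p = 0.0349) and Lyz2 (adjusted p = 0.00665).

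Splicing changed in 233 genes. The authors' deposited MAJIQ table compared experimental with control epidermis, with a single PSI per group, so values have no replicate error and rest on MAJIQ's posterior probability. In it 587 junctions or retained introns, in 265 splicing modules, had a probability of at least 0.95 that PSI changed by at least 0.15. Of 67 cassette exons past that probability, 44 were included less and 23 more in experimental epidermis, by the inclusion junctions past it. In 3 of them the other inclusion junction had the opposite sign: by 0.117 in Esrp1 and -0.185 in Etl4, whose direction is uncertain, and by 0.003 in Cd44, where the skipping junction rose by 0.775. Their median length was 84 bases, 54 of the 67 had a length divisible by 3, and 64 overlapped coding sequence in the GENCODE M21 annotation. Among 119 introns in intron events, 82 were retained more and 37 less. The table also held alternative first exon events in 52 genes and alternative last exon events in 33.

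Genes listed in advance from earlier studies as ESRP targets were prominent among these. Of 47 such genes 26 held a changed junction. Whether any of those studies used epidermis was not checked, so the overlap may in part repeat them. Over the 10682 genes tested for expression, which included 45 of these targets and 191 of the spliced genes, 0.805 shared genes would be expected, and the odds ratio was 86.9 (Fisher's exact test, two-sided, p = 1.16e-34). This background counts as unspliced every gene absent from the authors' MAJIQ results, including any that MAJIQ could not measure. Of the 236 genes in those results 233 were changed, so no set of measured but unchanged genes was at hand. The odds ratio may therefore be too high. The largest absolute change of PSI per target ran from 0.267 in Lrrfip2 to 0.843 in Atp6v1c2.

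The fibroblast growth factor receptor genes Fgfr2 and Fgfr3 switched between mutually exclusive exons that encode part of the ligand-binding domain. In Fgfr2 (chromosome 7, minus strand) the junction into the IIIb exon at 130199758 to 130199905, the epithelial form, fell from a PSI of 0.740 to 0.049, while that into the IIIc exon at 130198419 to 130198563, the mesenchymal form, rose from 0.004 to 0.633. In Fgfr3 (chromosome 5) the junction into the first of the pair, at 33731281 to 33731431, fell from 0.589 to 0.098, and that into the second, at 33732117 to 33732261, rose from 0.006 to 0.385. Each of these exons is annotated in GENCODE M21. Fgfr1, which averaged only 1.91 TPM, changed at a putative alternative 3' splice site junction, from 0.203 to 0.834. No mutually exclusive exons were derived for it.

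**Figure D4:**
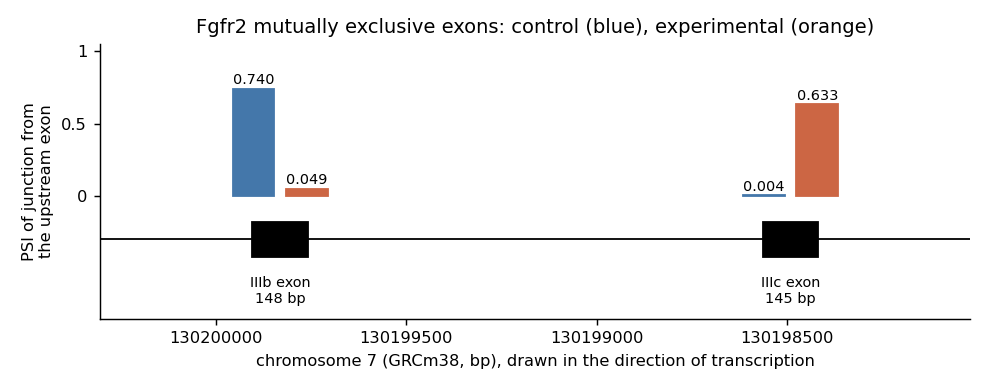
Map of the mutually exclusive Fgfr2 exons on chromosome 7 (GRCm38), to scale and in the direction of transcription, with bars for the PSI of the junction entering each exon, 1 value per group. The IIIb exon stood at 0.740 in control and 0.049 in experimental epidermis, the IIIc exon at 0.004 and 0.633.

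Other literature targets changed isoforms as well; for each exon the PSI given here is that of the inclusion junction with the larger change. Cd44, the hyaluronan receptor, used the junction from 102828610 to 102853015 on chromosome 2, which passes over its variable exons, at a PSI of 0.084 in controls and 0.838 in experimental epidermis. Enah, an actin regulator, lost its 63-base coding exon at 181911597 to 181911659 on chromosome 1, from 0.413 to 0.012. Ctnnd1, which encodes p120 catenin, gained the 289-base exon at 84624270 to 84624558 on chromosome 2, from 0.409 to 0.865. Scrib, a polarity protein gene, gained the 63-base exon at 76061739 to 76061801 on chromosome 15, from 0.144 to 0.908. Nf2, which encodes merlin, lost the 45-base exon at 4780578 to 4780622 on chromosome 11, from 0.767 to 0.110, and its other inclusion junction went from 0.420 to 0.020. Itga6, the integrin alpha 6 gene, lost the 130-base exon at 71853534 to 71853663 on chromosome 2, from 0.933 to 0.563. Each of these exons is annotated as coding in GENCODE M21.

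**Figure D5:**
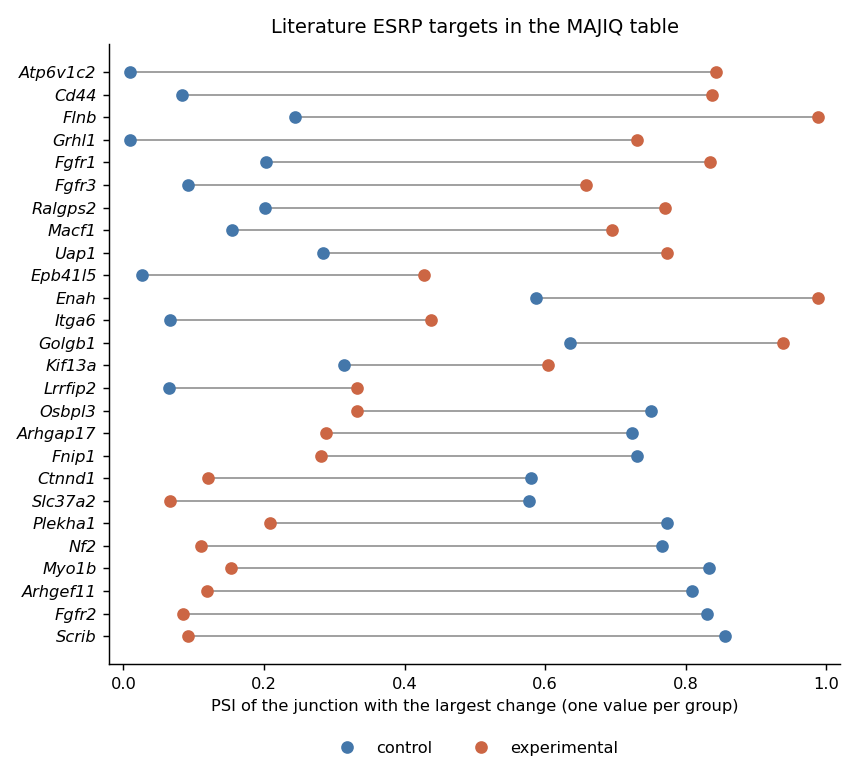
PSI of the junction or intron with the largest change in each of the 26 literature ESRP targets found in the authors' MAJIQ table, control in blue and experimental in orange, 1 value per group. The absolute changes run from 0.267 to 0.843.

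The 12 largest changes of PSI included cassette exons of Arhgef10l (skipping junction 0.113 to 0.993), Slk (0.075 to 0.939) and Atp6v1c2 (0.010 to 0.843), the last encoding a subunit of the vacuolar proton pump. Tlcd2 switched its distal 5' splice site junction from 0.023 to 0.991. Of the 12, 6 were introns marked as absent from the annotation, in Tspear, Ulk4, Polr2c, Zc3h11a, Samd4b and Ccnh, and they went both ways: Polr2c rose from 0.008 to 0.985 and Ulk4 fell from 0.993 to 0.009. The stretch marked as an intron in Tspear is very short, from 77759175 to 77759186 on chromosome 10. Whether it is a true intron was not tested. Ulk4 and Ptpn5 were listed at 0 TPM in all libraries and Tspear averaged 0.408 TPM, so these PSI values rest on genes at the floor of the expression table, and Zc3h11a was absent from it. Ptpn5, at an alternative last exon, and Esrp1 complete the 12.

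Genes with changed splicing were also changed in expression more often than others. Of 191 spliced genes tested, 12 were among the 263 changed genes against 4.70 expected (odds ratio 2.73, Fisher's exact test, two-sided, p = 0.0027). Here too, genes absent from the authors' MAJIQ results counted as unspliced. Without Esrp1 the odds ratio was 2.51 (Fisher's exact test, p = 0.00715). In quartiles of expression from lowest to highest the odds ratios were 3.74, 0.787, 2.51 and 4.41, with the highest quartile alone under 0.05 (Fisher's exact test, p = 0.00882). With the authors' deposited list in place of the limma calls it was 1.75 (Fisher's exact test, p = 0.0545). Grhl1 was among the 12, and in it the 77-base coding exon at 24582885 to 24582961 fell from a PSI of 0.820 to 0.113 at the inclusion junction with the larger change, a length that is no multiple of 3. Inf2, a formin gene, fell 1.37 on the log2 scale (SE 0.20, limma adjusted p = 0.0077) and its 57-base exon at 112612548 to 112612604 on chromosome 12 went from 0.665 to 0.282 at its downstream inclusion junction and from 0.725 to 0.465 upstream. Krt12 rose while an intron event in it changed by -0.383. The other members were Cyb561a3, Esrp1, Icmt, Ift57, Mapre2, Pde8b, Smarcd3, Tmem159 and Zfp385a, named because they make up this overlap and chosen after their values were seen.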

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

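The tests of explanations in this part were chosen after the results were seen, except the count over other splits of the libraries. Among 190 groups of 4 libraries checked for a library far from the rest, 21 were picked out where chance gives about 1 in 20, or 9.5. Control library 4 accounted for 9 and experimental library 2 for 8. The measure is the gap to the nearest library divided by the group's range, on the log2 scale. It is 1 by construction where all but 1 library of a group were at the floor, as for Fosl1, Gsta3 and Slc4a1 below. Means of lists were also checked beside their own members. The 9.5 is therefore only a rough guide. Control library 4 was highest for Esrp1 (162 TPM against 131 to 135, gap 0.843), Spink7 (0.927), Cyp11a1 (0.889), Sprr2h (0.867), Pxylp1 (0.94), Lce1k (423 against 229 to 239.9 TPM, gap 0.922), Smpd1 (0.883), Fosl1 (above the floor there alone, gap 1) and the mean of the cornified envelope list (0.917). Experimental library 2 was lowest for Sprr2d (268 against 293 to 297 TPM, gap 0.852), Lce1k (0.886), Cldn12 (0.863), Pkp3 (63.2 against 115 to 129 TPM, gap 0.846), Fabp4 (71.1 against 257 to 276 TPM, gap 0.946), and the means of the tight and adherens junction list (0.961), the desmosome list (0.872) and the adipocyte list (0.942). Experimental library 4 was lowest for Krt12 (0.914) and highest for Lyz2 (0.88). Gsta3 in control library 1 and Slc4a1 in experimental library 1 were above the floor in that library alone of their group, each with a gap of 1.

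The comparison of experimental with control gave 263 genes. Of the 35 splits of the 8 libraries into groups of 4, the real one included, 1 gave as many, and the highest other split gave 1 gene. With 35 splits the smallest possible share is 1 in 35. The other splits mix the groups, so a real difference would widen their spread and lower their counts. The real split thus stood apart from the others, but this count does not exclude chance.

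The rise of the alarm gene list was weighed against 5 explanations. For scaling of the TPM values, 17 members rose after centring and 16 after quantile normalization. Centring added 0.21 to every log2 change, so it could not lower the rises, and these counts do not decide against scaling. A shift common to all genes went the other way: the median gene changed by -0.18, where the list's median was 1.01. Other effects of scaling were not tested. An uneven share of follicle tissue predicts, from the slope within groups of the alarm list on the hair list, a difference of -0.0276 (95% interval -0.37 to 0.32), and an uneven share of basal cells, from the slope on the basal list, one of -0.0348 (95% interval -0.17 to 0.10), where 1.34 was observed. The experimental libraries rich in mitochondrial transcripts are not needed for it, since without libraries 2 and 4 the difference was 1.39. An effect of the transgenes apart from the deletion cannot be told apart from loss of Esrp1, because 0 libraries carried the transgenes with Esrp1 intact; the deletion itself may explain the rise, which stays a hypothesis.

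Lower hair and sebaceous gene levels could reflect how much follicle tissue each library held. A scaling shift common to all genes is argued against as the whole cause. Centring added 0.21 to every log2 change and left the median of the hair list at -1.52. If a shared amount of follicle tissue set both lists, libraries of 1 group with more hair transcript should hold more sebaceous transcript. The slope within groups was -0.24 (95% interval -0.78 to 0.30), which does not decide it, so this explanation and an effect of genotype cannot be told apart with 4 libraries per group. An exact permutation test of the hair list mean gave p = 0.0857 and of the sebaceous list mean p = 0.0286, the smallest possible, with adjusted values of 0.331 and 0.257 over 27 lists; the alarm and adipocyte list means had the same values as the sebaceous list, the adipocyte list being lower by 0.83.

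The excess of lower over higher genes may come from a few abundant genes that take a larger share of TPM in experimental libraries. Leaving the 10 most abundant genes of each library out of its total moved the median log2 change from -0.18 to -0.10, and leaving out 1 library at a time spread that value from -0.18 to -0.0027. This spread leaves open how much of the shift the share explains, which cannot be told apart from a lower level of many genes.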

How the results depend on the processing

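No paired analysis was possible because the columns of the expression table carry no replicate number; the fit with replicate number as a block was not run. Esrp1 was lower under every setting run, with adjusted p under 0.05 in all but 2 chosen after seeing the data: without experimental libraries 2 and 4 (log2 change -0.99) and without experimental libraries 1 and 3 (-1.27); leaving out 1 library gave -1.21 to -1.01. Genes past the threshold both in the reported analysis and in another setting kept their sign, while some named genes that did not pass changed sign between settings. The 263 changed genes became 55 at adjusted p under 0.01 and 172 with an absolute log2 change of at least 1. Library weights gave 4423 genes. Leaving out 1 library gave 85 (experimental library 3) to 578 (control library 4), with over 1.5 times fewer genes also without control library 2 (121) or 3 (91) and experimental library 1 (140), 2 (135) or 4 (101). Settings chosen after seeing the data gave 1597 (residual principal component), 552 (sex), 544 (without control libraries 1 and 2), 2595 (without control libraries 3 and 4), 15 (without experimental libraries 2 and 4) and 28 (without experimental libraries 1 and 3). Leaving out libraries changed the count both ways, and the cause was not tested. Experimental libraries 1 and 3 held Y-linked transcript and 2 and 4 did not. Leaving out either pair thus also left experimental libraries of a single sex.

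The 162 genes of the authors' list past the limma threshold became 107 at a mean of 5 TPM, where fewer were tested, 102 with centring, 485 with library weights, 46 to 306 without 1 library, and, chosen after seeing the data, 479 (principal component), 415 (without control libraries 3 and 4), 1 (without experimental libraries 2 and 4) and 9 (without experimental libraries 1 and 3). All of its tested genes kept a negative sign in every setting but the one without control libraries 3 and 4 (99.8%).

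Of 11 lists past camera's threshold 6 passed with quantile normalization, 1 with an estimated correlation, 1 with fry and 0 with an estimated correlation and centring; leaving out 1 library gave 8 to 13. Direction in camera is relative to other genes. Tight and adherens junctions and cell cycle genes were downward but not called in the reported analysis (camera adjusted p = 0.642 and 0.919). Direction reversed for tight and adherens junctions, upward with library weights (adjusted p = 0.0223) and without control libraries 3 and 4 (0.0223). In the latter fit 1 junction gene rose and 2 fell, while the median gene changed by -0.34. Direction also reversed for cell cycle genes, upward without control libraries 1 and 2 (9.16e-09) but downward without control libraries 3 and 4 (2.61e-11). Epithelial transcription factors reversed to downward and uncalled with fry (0.994). The values for tight and adherens junctions and for cell cycle genes are those of camera at the preset correlation. Estimated correlations over all libraries were 0.461 and 0.923, so these p-values may be far too small and the reversals are uncertain. The alarm list passed in all settings but estimated correlation with centring. No named gene past the threshold reversed.

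The 587 changed junctions became 383 at an absolute change of at least 0.3; they lay in 233 genes and 351 local splicing variations. The odds ratio of spliced among changed genes was 1.75 with the authors' list, no longer past the threshold. Depth was unknown, so its limit on low genes could not be set beyond the floor of 1 TPM.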

Other observations

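The tests in this part were chosen after the results were seen. The epidermal differentiation complex, a cluster of envelope and S100 genes on chromosome 3, was examined as a region. Between S100a1 and S100a10 (90511034 to 93564643, GRCm38) 59 genes were tested, of which 16 rose and none fell, and 44 had log2 changes above 0, with a median of 0.70. The region was chosen because listed genes in it were among the largest rises, so the genes outside the fixed lists were tested apart. A hypothesis is that the region changed beyond the listed genes: of its 20 unlisted genes 4 rose, an odds ratio of 36.3 against unlisted genes elsewhere (Fisher's exact test, two-sided, p = 1.11e-05). The count is small, and neighbouring genes are not independent. Lce6a, the 1 named gene among these 4, belongs to a family that the lists hold in part, and the families of the other 3 were not examined, so the test does not show a change beyond the listed families. Lce6a rose from 655 ± 142 to 1215 ± 84.5 TPM (SD, n = 4 each; limma adjusted p = 0.0417).

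A hypothesis was that part of the intron events come from genes of low expression. Of 100 genes with an intron event in the authors' MAJIQ results, 13 were not in the expression table, and 13 of the other 87 averaged 1 TPM or less, against 1 of 62 genes with a cassette exon event (odds ratio 10.7, Fisher's exact test, two-sided, p = 0.0081). The values this hypothesis needs are there, for a small part of the intron genes, and low expression alone does not show that an event is false. Unannotated junctions or introns made up 34.8% of the 587 past the probability threshold.

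Grhl1 lost a coding exon whose length is no multiple of 3 and also fell in level, and a hypothesis was that such exons go with lower transcript level in general. Genes with a changed frame-shifting cassette exon (11) had a median log2 change that differed by -0.0204 from that of genes with a frame-keeping one (45; permutation test, two-sided, p = 0.839). The test gave no evidence for the hypothesis, and with 11 genes a small effect may have been missed. It also pooled exons included more with exons included less, so opposite effects could cancel, and it does not decide the case of lost exons.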
